A study of Homo sapiens with 6 samples.

How the data were processed

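Chromatin of ACHN cells was fixed, sonicated and precipitated, and the libraries were sequenced as read pairs, per the labels' protocols. Of 6 samples, 4 ChIP libraries had a peak list, for 2 antibodies (H3K27me3 and EZH2) and 2 genotypes (ZCCHC8-WT and ZCCHC8-KO), and the 2 input libraries entered only as the controls of the lists. Groups came from the genotype and title labels. There was 1 library per group. Reads were trimmed with cutadapt 1.9.3 and aligned with Bowtie2 2.2.4 to hg38, as far as the submitters' processing notes name these tools; the peak caller and read depths are not given in the sources used here.

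Each deposited list had 6 columns without a header. The fifth held the peak's length in bp as deposited, equal to end minus start plus 1, so coordinates were read as 1-based. The sixth held the authors' score for each peak, whose definition is not given in the sources used here, so scores were used only to rank or filter peaks, and thresholds on them may not mean the same in WT and KO lists. Peaks were listed on 1 to 81 identical lines and were counted once. The peak names carry a p threshold of 1e-3.

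Covered length, overlaps (minimum 1 bp), the share of WT peaks shared with KO, and covered shares of gene windows were computed with Python 3.11.15, NumPy 2.4.6, pandas 2.3.3 and SciPy 1.17.1; figures were drawn with matplotlib 3.10.9. Backgrounds were 100 circular shifts along each chromosome and 100 shifts by 20 to 200 kb. Gene lists were set against 10000 random lists matched on WT covered share in 10 classes, which describes these libraries only. The routines were tested on simulated data: among 20037 genes, 200 of 200 genes stripped of their peaks were called lost, for each antibody.

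The design, the gene lists, the alternative settings listed first and the rule for named genes were set before the data were examined. Alternatives changed the score threshold, the overlap that counts as shared, the stitching, the gene window and the chromosomes used. The rule took, per antibody, the 10 protein-coding genes with the largest deficit and the 10 with the largest excess of covered share in KO, neighbours sharing a window counted once; of each of 17 fixed lists the 2 members with the largest deficit and excess (a selection of these is printed); ZCCHC8, EZH2, SUZ12, EED, RBM7 and MTREX always; and the 5 widest WT domains (stitched across 3 kb) and 5 100-kb bins per direction, of which a selection is printed. KLF14, LBX1 and HAND1 were named after their values were seen, and so was the description of POU3F3, which shares the window of a gene the rule takes.

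Several steps departed from the design. The gene table used here (GRCh38.p14) gives neither strand nor exons, so windows of 5 kb around both gene ends, merged where they meet, replaced windows around transcription starts, and peaks were placed as within 1 kb of a gene end, inside a gene, near it or farther away instead of by promoter, exon and intron. Gene body and upstream sequence was replaced by the gene with 5 kb on both sides. Base composition of EZH2 peaks was not analysed here.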

Results

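The series asks how the NEXT complex, a nuclear adaptor that hands short-lived RNAs to the RNA exosome, relates to the repressive histone mark H3K27me3. ZCCHC8 is the scaffold protein of NEXT. ACHN cells, a human renal carcinoma line, with intact ZCCHC8 (WT) or with ZCCHC8 knocked out (KO) were profiled by chromatin immunoprecipitation and sequencing with antibodies against H3K27me3 and against EZH2, the catalytic subunit of Polycomb repressive complex PRC2. There was 1 library per antibody and genotype, and 1 input library per genotype, so no difference has a replicate check and none was tested between genotypes. The values are peak positions in 4 lists, and the read depth behind each list is not given in the sources used here. Intervals of shares are exact 95% Clopper-Pearson intervals and cover counting error only; bootstrap ranges over chromosomes are named as such.

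H3K27me3 peaks were fewer in the KO list and of similar width, with a median of 269 bp in WT and 265 bp in KO. The WT list held 93095 peaks covering 31.7 Mb and the KO list 69840 peaks covering 23.2 Mb, a KO/WT ratio of 0.750 for number and 0.732 for covered length. The widest block of difference lay on chromosome 7, where 12255 WT peaks stood against 4897 KO peaks (ratio 0.400). Within it, the 100-kb bin at 78400001 to 78500000 inside MAGI2, a synaptic scaffold gene, held 67 WT peaks covering 36979 bp and 2 KO peaks covering 496 bp. A bin at 121800001 to 121900000 over PTPRZ1, a receptor tyrosine phosphatase of the nervous system, held 51 and 7 peaks.

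The ratio was not uniform over the genome. H3K27me3 peaks were fewer in KO on 17 of 23 chromosomes (1 to 22 and X) and more numerous on chromosomes 16, 17, 19, 20, 21 and 22, with the highest ratio, 1.42, on chromosome 20. Chromosome 7 alone held 31.6% of the net difference, and without it the ratio of peak numbers was 0.803. Within chromosomes, the KO/WT ratio of 5-Mb bins was higher where protein-coding genes were denser, with a mean Spearman rho across bins of 0.422 over 22 chromosomes and a rho above 0 on all 22. Only bins with 10 or more WT peaks entered, on chromosomes with at least 8 such bins, which left out chromosome 19. Bins are not independent replicates. The ratio was 0.307 when peaks below a score of 7, the WT median, were left out of both lists; the lowest score listed was 5 in WT and 4 in KO.

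**Figure D1:**
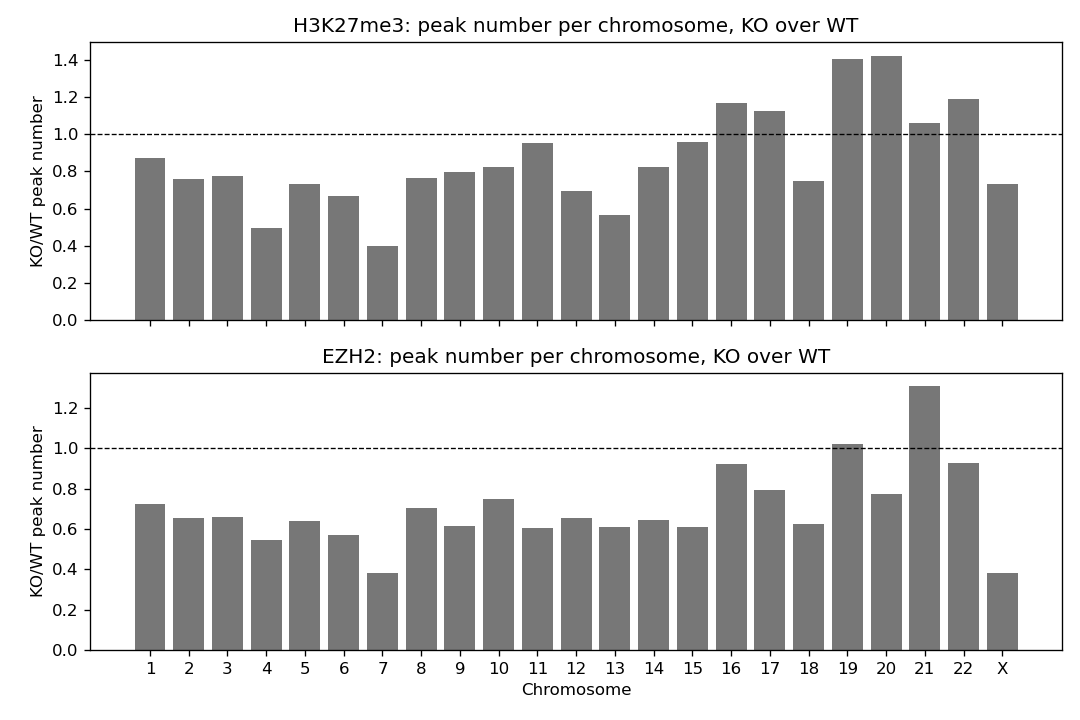
Ratio of KO to WT peak number (y axis, no unit) on each chromosome (x axis) for H3K27me3 (top) and EZH2 (bottom), with 1 library per antibody and genotype and hence no error bars; the dashed line marks equal numbers. Chromosome 7 lies at 0.400 with H3K27me3 and 0.382 with EZH2, and chromosomes 16, 17, 20 and 22 lie above the line with H3K27me3 and below it with EZH2.

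Most H3K27me3 peaks were listed in 1 genotype only. Of the WT peaks, 15.9% (15.6 to 16.1) overlapped a KO peak by at least 1 bp, against 1.97% after circular shifts of the list and 4.74% after shifts of 20 to 200 kb. In the reverse direction 21.4% (21.1 to 21.7) of KO peaks overlapped a WT peak. Sharing varied with the score, as 6.59% of WT peaks with a score of 5 and 86.5% of those with a score of 20 to 29 were shared. Of KO peaks, 12.4% with a score of 4 to 5, 79.9% with a score of 15 to 19, 68.2% with a score of 20 to 29 and 49.4% with a score of 30 or more overlapped a WT peak. Sharing was also tied to width, from 8.95% of WT peaks of 170 to 249 bp to 84.9% of those of 2000 bp or more. The score is the authors' own value for each peak. With 1 library per group, the share expected between repeats of the same genotype is unknown for either antibody. Low sharing is therefore no measure of turnover between WT and KO.

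An H3K27me3 peak lay within 5 kb of an end of 3916 of 20037 protein-coding genes in WT and of 3446 in KO. Of the WT-marked genes, 2351 (60.04%, 58.5 to 61.6) were also marked in KO, against 19.3% expected if the lists were unrelated, while 1565 were marked in WT only and 1095 in KO only. The gene with the highest coverage in both lists was KLF14, an imprinted Krüppel-like factor gene on chromosome 7, with 61.3% of its window covered in WT and 53.2% in KO. No gene differed by 50 percentage points of its window, the size fixed for a large difference.

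Of the 10 genes with the largest H3K27me3 deficit in KO, 4 lay on chromosome 7, namely LRGUK, HEPACAM2, VWDE and THSD7A. LRGUK, needed for sperm tail formation, had 43.4% of its window covered in WT and 10.0% in KO, and HEPACAM2, a cell adhesion gene, 40.6% and 9.18%. CR2, the complement receptor of B cells, went from 44.1% to 13.4%, and CLEC12B, an inhibitory C-type lectin receptor, from 31.5% to 4.45%. VWDE had 25.4% and no coverage, THSD7A, an endothelial thrombospondin-domain gene, 28.7% and 3.96%, and SLC38A4, an amino acid transporter, 24.1% and no coverage. The defensin gene DEFB105B, whose window overlaps that of DEFB106B, had 42.7% and 15.1%, and the cyclophilin-like genes PPIAL4G and PPIAL4C had 33.5% and 5.84%, and 35.3% and 8.96%. The defensin and PPIAL4 genes have near-identical copies, so their values are uncertain.

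The largest H3K27me3 excesses in KO were smaller. RAB6C, a retrocopy whose reads can be shared with related genes and whose value is therefore uncertain, had 10.4% in WT and 34.1% in KO. The epidermal keratin gene KRT77 had 0.925% and 21.8%, and ACOXL, an acyl-CoA oxidase-like gene, 2.53% and 22.5%. LOC124908045, a predicted gene inside POU3F3, had no coverage in WT and 19.5% in KO. GPR55, a lipid receptor, had 10.3% and 26.6%, and FOXB1, a forkhead factor of the developing brain, 11.7% and 27.9%. CLEC4D, a myeloid lectin receptor, had 18.5% and 34.6%, HLA-DQA2, an MHC class II gene, 6.26% and 22.3%, and PGLYRP4, which binds bacterial peptidoglycan, 17.8% and 33.6%. DEFB103A, with near-identical copies and so uncertain, had 7.80% and 24.8%.

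Among the gene lists fixed beforehand, developmental transcription factors, signalling genes and neuronal genes were H3K27me3 targets in both genotypes. Of 90 developmental factors, 41 were marked in WT and 38 in KO, with 25 marked in both; windows of the same size would give 16.5 and 15.1. DLX6, a limb and forebrain homeobox gene, had 19.3% in WT and 5.65% in KO, and NEUROG2, a proneural factor, 15.5% and 7.07%. NKX2-5, a heart factor, had no coverage in WT and 10.1% in KO, and DLX5 had 6.30% and 14.8%. Of 41 signalling ligands and receptors, 19 and 18 were marked. WNT2 had 16.3% and 5.39% and BMP2 10.5% and 0.890%, while WNT8B had 24.6% and 30.5% and WNT6 no coverage and 4.44%. Of 36 neuronal genes, 18 and 14 were marked, with CNTNAP2, a neurexin family gene, at 11.5% and 1.00%, and GAD2, which makes GABA, at 7.19% and none. The glutamate receptor gene GRIA1 had 0.910% and 5.77% and GABRB1 1.33% and 5.53%. DLX6, WNT2 and CNTNAP2 lie on chromosome 7, where the KO/WT ratio of H3K27me3 covered length was 0.342. DLX5, which was higher in KO, lies there too.

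Kidney genes had more H3K27me3-marked members in KO, 8 of 46 in WT and 17 in KO, with 7 marked in both and 10 in KO only. SLC5A12, a tubular lactate transporter, went from no coverage to 4.50% and WT1, a podocyte and kidney progenitor factor, to 2.94%, whereas CDH6 had 13.95% and 8.74% and EMX2 5.18% and 1.25%. The mean change of the kidney list was 0.0929 points, -0.379 with scores below 7 left out of both lists and -0.0851 over whole genes. Of 36 cell cycle inhibitors and tumour suppressors, 10 were marked in WT and 4 in KO. Coverage was lower in KO for WIF1, a secreted WNT inhibitor (43.4% and 25.6%), and UNC5C, a netrin receptor (8.09% and 1.69%). Of 28 epithelial and mesenchymal genes, 8 and 4 were marked, with FN1 at 5.45% and 0.870%, PRRX1 at 3.48% and none, MMP2 at 2.79% and 7.32% and GRHL2 at 2.99% and 3.31%. Of 39 HOX genes, the same 5 were marked in both genotypes, among them HOXD1 (16.9% and 7.25%), HOXC13 (12.4% and 7.57%) and HOXC12 (2.69% and 9.09%).

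Of 22 blood cell genes 9 and 6 were marked, with IKZF1, on chromosome 7, at 7.74% and 2.33% and CD3E at 1.51% and 6.74%. Of 18 muscle and heart genes 7 and 9 were marked, with MYOG at 12.6% and 5.89%, ACTC1 at 5.25% and none and MYOD1 at none and 5.05%. Of 24 imprinted genes 6 and 5 were marked, with ZDBF2 at 3.07% and none and MEST, on chromosome 7, at 6.76% and 9.56%. Among 32 Polycomb subunit genes 4 and 3 were marked, with CBX7 at 3.41% and none and CBX2 at 1.06% and 6.72%. Of 25 NEXT, PAXT and exosome genes 1 was marked in both, C1D (4.69% and 0.930%). Of 37 housekeeping genes 1 was marked in WT, PSMB2 (4.28%), and none in KO. Of 18 long non-coding RNA genes 4 were marked in each genotype, with MIR17HG at 3.89% and none and HOTAIR at 0.960% and 5.54%. Olfactory receptor genes were often marked, 157 of 390 in WT and 113 in KO, with OR2A14, on chromosome 7, at 18.96% and 1.36%. In the protocadherin clusters 3 of 53 genes were marked in WT and none in KO, and among 240 zinc finger genes of chromosome 19 none and 2. ZCCHC8, EZH2, SUZ12, EED, RBM7 and MTREX, the genes of the NEXT and PRC2 cores, had no peak of either antibody within 5 kb of a gene end in either genotype. Inside the gene, EED and EZH2 had 1 EZH2 peak each in WT and none in KO. The median change was 0 in each of the 17 lists with both antibodies. In most lists the majority of members were unmarked in both genotypes, so their median could only be 0.

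EZH2 peaks were also fewer in the KO list. The WT list held 30734 peaks covering 7.63 Mb and the KO list 19566 peaks covering 5.39 Mb, ratios of 0.637 and 0.706. Peaks were fewer in KO on 21 of 23 chromosomes, and chromosome 7 again had a low ratio (0.382, 3963 and 1513 peaks), next to X (0.383, 149 and 57 peaks). Of the WT peaks, 5.13% (4.89 to 5.38) overlapped a KO peak, against 0.462% after circular shifts and 0.929% after shifts of 20 to 200 kb. With the WT list cut to its 19566 top-scoring peaks, the size of the KO list, the covered length ratio was 1.02. Numbers were then equal by construction, so that ratio compares peak widths only. With a score of 7 or more in both lists the ratio of peak numbers was 0.206.

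Sharing of EZH2 peaks with their score differed by direction. Of WT peaks with a score of 20 to 29, 33 of 44 were shared, against 1.03% of those with a score of 5. Of KO peaks, 47.3% with a score of 12 to 14, 19.6% with a score of 20 to 29 and 9.94% with a score of 30 or more overlapped a WT peak. Many of the highest-scoring KO peaks lay clustered at few places. Of 104 with a score of 50 or more, 23 lay in 1 stretch of chromosome 1, and 12 and 11 in separate stretches of chromosome 16. Whether these clusters reflect EZH2 binding was not tested. Peaks of 500 bp or wider numbered 1093 in WT and 1057 in KO, and 34.6% of those in WT overlapped a KO peak. Of 3008 genes marked in WT, 1081 (35.9%, 34.2 to 37.7) were marked in KO, with 1927 marked in WT only and 902 in KO only, and 11.8% expected if the lists were unrelated. LBX1, a homeobox gene of muscle precursors and spinal neurons, was the most covered gene in both lists, at 47.8% and 46.0%, and HAND1, a heart and trophoblast factor, had 28.1% and 25.6%.

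Among the 10 largest EZH2 deficits in KO, GSX2, a forebrain patterning gene, had 34.4% of its window covered in WT and 8.62% in KO, and HOXC13, a hair follicle HOX gene, 29.3% and 5.26%. GBX1 had 27.2% and 8.15%, NKX1-2 24.7% and 5.86%, and HMX3, an inner ear factor, 31.3% and 13.7%. PRDM13, a regulator of spinal and retinal neurons, had 18.9% and 3.08%. TMEM229A (17.9%) and SLC7A14 (17.0%), a lysosomal amino acid transporter, had no coverage in KO. CR2 had 19.8% and 3.34%, and the predicted gene LOC124908046 24.8% and 8.81%. GBX1 and TMEM229A lie on chromosome 7, where the KO/WT ratio of EZH2 covered length was 0.408.

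The largest EZH2 excess in KO lay at POU3F3, a POU-domain factor of the developing brain and kidney, on chromosome 2. Its window had no coverage in WT and 31.9% in KO, and LOC124908045 within it had none and 32.2%. From 104841330 to 104873018, 20 EZH2 peaks and 12 H3K27me3 peaks were listed in KO and none in WT, while the 100 kb on the left and right held 8 and 13 WT H3K27me3 peaks and 1 and 1 WT EZH2 peaks. Peak lists do not show whether this stretch was present in the WT cells or covered by reads there. EN1, a midbrain patterning gene, had 11.4% and 33.9%, NEUROD2, a neuronal differentiation factor, 17.3% and 32.9%, and EVX1, on chromosome 7, 16.9% and 29.5%. CCND2, which encodes cyclin D2, had 8.23% and 25.7%. RIC3, a chaperone of acetylcholine receptors, had 1.79% and 16.7%, SYT2, a synaptic vesicle calcium sensor, 1.54% and 15.6%, and SYPL2 1.21% and 14.5%. PLA2G7, a lipoprotein-associated phospholipase, had none and 14.4%, and NAV2, a neuron navigator gene, 9.34% and 21.7%.

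**Figure D2:**
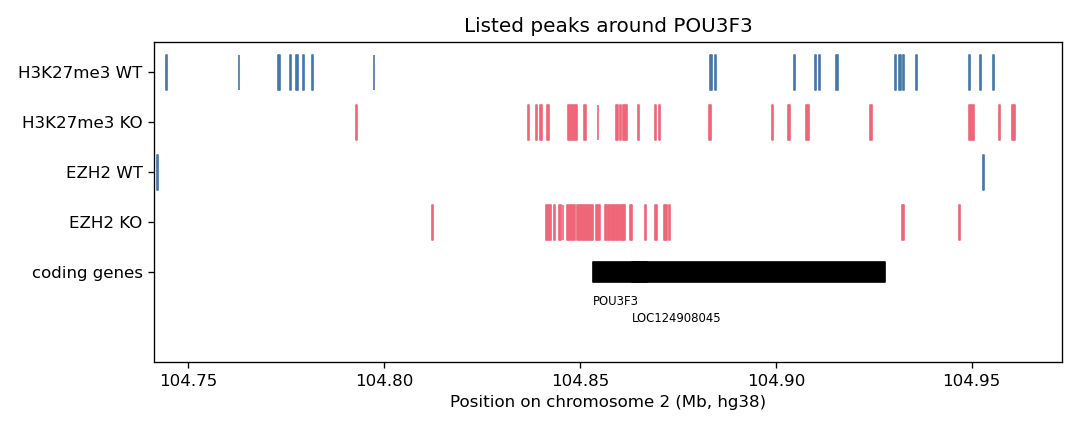
Peaks listed for H3K27me3 and EZH2 in WT (blue) and KO (red) cells along chromosome 2 (x axis, position in Mb, hg38), with protein-coding genes as black bars in the lowest track and 1 library per track. At the left end of the POU3F3 bar both KO tracks hold a cluster, 20 EZH2 and 12 H3K27me3 peaks, and both WT tracks hold none.

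Developmental transcription factors held EZH2 in both genotypes. Of 90, 52 were marked in WT and 49 in KO, against 12.3 and 8.38 for windows of the same size, and 38 were marked in both. The mean covered share was 3.54% in WT and 3.82% in KO. Among 10000 random lists with matched WT coverage, the mean change lay at percentile 100 and the median, which was 0, at 60.7. Of the 90 members, 29 had a higher and 34 a lower covered share in KO, so the higher mean was not shared across the list. The members with the largest deficits were DLX6, on chromosome 7 (16.7% and 6.17%), and LHX2, a forebrain and limb factor (16.8% and 9.35%). EN1 and EVX1 had the largest excesses (22.5 and 12.5 points), and the mean change was not computed without them. The mean change was -0.969 points when scores below 7 were left out of both lists.

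Of 39 HOX genes, 7 were marked by EZH2 in WT and 3 in KO. Their mean covered share was 1.80% in WT and 0.285% in KO, with the mean change at percentile 0.33 of matched random lists and the median, which was 0, at 50. With 32 of 39 members unmarked in both genotypes, that median could only be 0. The members with the largest deficits, HOXC13 and HOXC12 (18.1% and 4.22%), are neighbours on chromosome 12, and without them the mean change was -0.575 points in place of -1.52. No percentile was computed for the list without them. Of 36 neuronal genes, 15 were marked in WT and 5 in KO, with CNTNAP2, on chromosome 7, at 5.39% and none and KCNC2 at none and 1.73%. Of the tumour suppressor list 11 and 4 were marked, with UNC5C at 4.91% and none and CDH13, an atypical cadherin, at 2.17% and none. The mean changes of the neuronal and tumour suppressor lists lay at percentiles 53.15 and 43.15 of matched random lists. Of the signalling list 26 and 22 were marked, with WNT2, also on chromosome 7, at 15.1% and 2.80% and WNT10B at 15.3% and 8.85%. WNT1 had 11.4% and 19.3% and WNT7A 3.30% and 8.58%.

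In the other lists, EZH2 marked 13 kidney genes in WT and 10 in KO, with EMX2 at 33.0% and 26.9%, CITED1 at 6.45% and 1.30% and SALL1 at none and 3.17%. It marked 5 and 3 epithelial and mesenchymal genes, 8 and 7 blood cell genes and 7 and 5 muscle and heart genes, among them ACTA1, skeletal muscle actin (7.04% and 1.32%). Of the Polycomb genes 6 and 4 were marked, with BMI1 at 10.8% and 7.32%. Of imprinted genes 4 and 2, of long non-coding RNA genes 4 and 2 and of olfactory receptor genes 38 and 30 were marked. Of exosome-related genes none and 1, of housekeeping genes 1 and none and of chromosome 19 zinc finger genes 2 and 1 were marked, and no protocadherin gene was.

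EZH2 and H3K27me3 peaks coincided more often than shifted peaks in both genotypes. In WT 13.97% (13.6 to 14.4) of EZH2 peaks overlapped an H3K27me3 peak, against 2.59% after circular shifts and 4.75% after local shifts, and in KO 18.997% (18.4 to 19.6), against 1.86% and 4.81%. Among genes with an EZH2 peak, 55.1% in WT and 63.1% in KO also had an H3K27me3 peak, compared with 13.3% and 12.2% of genes without. Both lists of a genotype were called against the same input, so part of the overlap may come from that input.

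H3K27me3 was listed again in KO more often where EZH2 was. Within WT EZH2 peaks that overlapped a KO EZH2 peak, 50.6% of the WT H3K27me3 length was also covered in KO, against 19.2% within WT EZH2 peaks that did not, a difference of 31.4 points (23.7 to 38.1 over 1000 bootstrap draws of chromosomes). The difference was 18.8 points for 5 kb on both sides of the peak midpoint. The shares at the peaks themselves rest on 611 and 3684 WT EZH2 peaks with H3K27me3 in WT. Sharing of H3K27me3 peaks varied with their score and width, which were not matched here. Both lists of a genotype also share an input, so losses of both can share its errors. The difference therefore does not show that the mark follows EZH2.

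The widest stitched WT domains of H3K27me3 with a gene lay over SEMA3D, an axon guidance gene on chromosome 7 (45.8% covered in WT and 15.8% in KO), WIF1 (50.5% and 33.9%) and PNLIP, pancreatic lipase (34.9% and 27.7%). The other 2 of the 5 widest lay on chromosome 2 between 92328680 and 92577573 without a protein-coding gene. For EZH2 they lay over FLI1, an ETS factor of blood and endothelium (39.5% and 18.1%), LOC124908046, HOXC13 (33.5% and 5.72%), the potassium channel gene KCNA1 (19.3% and 17.1%) and LBX1 (46.5% and 46.7%). By bin, H3K27me3 was higher in KO at 5000001 to 5100000 on chromosome 12 with KCNA5 (23 WT and 50 KO peaks) and at 110700001 to 110800000 on chromosome 2 with ACOXL (29 and 57). EZH2 bins lower in KO included GRM8, a glutamate receptor gene (11 and 4 peaks), and SLC7A14 (12 and none).

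By place, 61.7% of H3K27me3 peaks in WT and 61.8% in KO lay farther than 5 kb from protein-coding genes. For EZH2 the shares were 52.4% and 56.5%. Protein-coding genes with 5 kb on both sides take 45.1% of the chromosomes, and the rest lies farther away. Within 1 kb of a gene end, a zone that takes 2.36% of the chromosomes, lay 1.55% and 1.72% of H3K27me3 peaks and 3.23% and 3.15% of EZH2 peaks.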

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

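The test of shared peaks on chromosome 7 and the test with matched peak scores were chosen after the result was seen; the other tests below were written before their results were computed.

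On 4 chromosomes the peak numbers of the antibodies went opposite ways between WT and KO, and the difference itself was not tested. The KO/WT ratios with H3K27me3 and EZH2 were 1.17 and 0.923 on chromosome 16, 1.13 and 0.792 on chromosome 17, 1.42 and 0.772 on chromosome 20, and 1.19 and 0.927 on chromosome 22. By covered length the antibodies went the same way on chromosomes 16 (1.21 and 1.06) and 22 (1.21 and 1.08). They went opposite ways by length only on chromosomes 17 (1.09 and 0.885) and 20 (1.43 and 0.887).

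The KO/WT ratio of H3K27me3 peaks tended to be higher on gene-dense chromosomes (Spearman rho 0.644 across 23 chromosomes), with exceptions such as chromosome 12 (7.68 genes per Mb, ratio 0.694) and chromosome 21 (5.12 genes per Mb, ratio 1.06). A library bias that follows gene density predicts the same trend inside chromosomes, and it was there: the mean within-chromosome Spearman rho between gene number and the log2 KO/WT ratio of 5-Mb bins was 0.422 with H3K27me3 (0.355 to 0.503 over bootstrap draws of chromosomes). The values this bias needs are thus present, although a real shift of the mark towards gene-rich regions would give them too. For a move of EZH2 itself the mean rho was 0.098 (0.0129 to 0.169) over 19 chromosomes, with a rho above 0 on 13. That range spans the bound of 0.1 set for the absence of a move, so this stays open. Weighing the bootstrap range was added after the value was seen. An effect of genotype cannot be separated from a difference between single libraries.

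Chromosome 7 had the lowest KO/WT ratio of peak numbers with both antibodies, 0.400 and 0.382, with X at 0.383 for EZH2. It also had the highest WT density, 76.9 H3K27me3 and 24.9 EZH2 peaks per Mb, just above chromosome 12 (71.0 and 24.7). In KO its densities were 30.7 and 9.50, against 28.8 and 9.19 on chromosome 1 and 49.3 and 16.2 on chromosome 12. The ratio alone does not tell an excess in the WT lists from a deficit in the KO lists. If lower sensitivity of the whole KO library were the cause, WT peaks of chromosome 7 would be shared with KO about as often as WT peaks of the same score and width elsewhere; the observed over expected number was 0.598 with H3K27me3 and 0.604 with EZH2, -1.15 and -0.907 SDs from the mean of the other 22 chromosomes. With a spread this wide, a value 2 SDs below the mean would be 0.308 and 0.139, so a 2-fold deficit would not have been seen and the test decides nothing. An earlier test, the distance of the chromosome 7 ratio from the other 21 autosomes (-2.80 and -2.89 SDs), was dropped because it restates the pattern, and lower sensitivity stays open. A different copy number or input coverage of chromosome 7 in the KO cells predicts a fall along the whole chromosome: 90.3% of its 5-Mb bins lay below the median of other chromosomes with H3K27me3 and 77.4% with EZH2, short of the 80% set for both and above the 65% set against it, so copy number, input coverage and a biological loss cannot be told apart without the input reads, which were not analysed here.

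Developmental transcription factor genes often stayed marked by EZH2 while the whole peak list shrank, with 38 of 52 WT-marked members (73.1%) also marked in KO. The WT and KO peaks in a gene's window need not overlap. The share kept lay at percentile 98.9 of random lists matched on WT covered share, whose mean was 59.9%. It lay at percentile 99.96 of lists matched on the highest WT peak score. Covered share and score were matched separately, on values observed without a replicate. These tests therefore cannot decide whether a stronger underlying WT signal at these genes is the whole cause. Chromosomes that kept more peaks are argued against by percentile 100 of lists matched on chromosome. Matching on covered share took up much of the gap from the 35.9% of all marked genes. Other lists varied: 17 of 26 WT-marked signalling genes and 6 of 8 blood cell genes were also marked in KO, but 4 of 15 neuronal genes and 4 of 11 tumour suppressors. With H3K27me3, 25 of 41 WT-marked developmental factors were also marked in KO, near the 60.04% of all WT-marked genes. A retention of EZH2 at the developmental genes may be biological, as a hypothesis found and tested on the same libraries. Local read depth was not tested, and stronger WT signal stays open.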

How the results depend on the processing

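The alternatives at 500 bp, without scores of 50 or more, for whole genes, without chromosome 7, without HOXC12 and HOXC13 and with WT shares scaled by chromosome were chosen after seeing the data, as was the tolerance of 1 point for gene lists. Of 428 alternatives for 89 results, those not named here stayed within 1.5 times the count or ratio, within the 95% interval of the share or within 1 point for lists, except 5 list means that moved by more than 1 point in the same direction. Leaving out replicates was impossible with 1 library per group, and so no paired analysis was possible. A threshold on -log10 p, other contigs and the sequence alternatives were not run. The cause of the changes below was not tested. Limits of depth are unknown, since no depth is given in the sources used here.

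With a score of 7 or more in both lists, the KO/WT ratio of H3K27me3 was 0.307 for number and 0.362 for length, and of EZH2 0.206 and 0.279; the share of WT peaks shared was 10.5% and 4.14%, genes marked in KO only were 332 and 162, and WT-marked genes kept were 36.3% and 21.6%. With that score in WT only, 19.2% and 6.84% were shared. With the WT lists cut to as many top peaks as the KO lists hold, the EZH2 length ratio reversed to 1.02, and the KO peaks shared were 19.1% and 6.93%. With numbers made equal, that length ratio compares widths and cannot show whether fewer places were occupied. For EZH2 peaks of 500 bp or wider the ratio of numbers was 0.967, and 38.8% of such H3K27me3 and 34.6% of such EZH2 WT peaks were shared. Reciprocal overlap of 50% gave 5.40% and 2.06%, a distance of 1 kb 34.4% and 12.02%, and stitching 21.1% for H3K27me3. Within 1 kb of gene ends, H3K27me3 marked 784 genes in WT only and 622 in KO only with 39.3% kept, and EZH2 689 and 373 with 26.9% kept. With 20% of the window covered the counts were 65 and 32 with 38.7% kept for H3K27me3, and 13 and 10 for EZH2. Whole genes gave 69.7% and 46.8% kept. EZH2 peaks on H3K27me3 were 9.20% in WT and 12.8% in KO with 50% of the peak covered, 16.0% and 21.1% from the median score up, and 20.3% and 25.8% with stitching. The H3K27me3 difference at EZH2 peaks was 18.8 points around midpoints. Peaks within 5 kb of a gene end were 8.94% in WT and 10.0% in KO for H3K27me3 and 15.1% and 15.7% for EZH2, and by length 3.81% and 3.66% of EZH2 lay within 1 kb. In place of medians of 0, the mean was -1.04 points for tumour suppressors with H3K27me3 and -1.52 for HOX genes with EZH2.

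Mean list changes reversed, in points, in these cases. Within 1 kb, H3K27me3 gave 1.10 for HOX genes, 0.510 for developmental factors, 0.0542 for signalling, 0.634 for muscle, 0.507 for imprinted and -0.369 for long non-coding RNA genes; EZH2 gave -0.0877 for developmental factors, 0.176 for imprinted and 0.0189 for zinc finger genes. Whole genes with H3K27me3 gave 0.0632 for developmental factors, -0.0851 for kidney, 0.0880 for blood, 0.0788 for imprinted and -0.0144 for long non-coding RNA genes. The stricter score gave -0.379 for kidney and -0.143 for Polycomb genes with H3K27me3, and -0.969 for developmental factors with EZH2. Scaling by chromosome gave 0.0271 for HOX genes, 0.563 for developmental factors, 0.206 for signalling, 0.212 for muscle and 0.205 for imprinted genes with H3K27me3, and with EZH2 0.0488 for epithelial and mesenchymal, 0.722 for signalling, 0.0159 for imprinted, 0.0303 for long non-coding RNA and 0.0220 for olfactory receptor genes. Without chromosome 7, imprinted genes gave 0.00125 with EZH2.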

Other observations

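The POU3F3 values and the high-score places below were singled out after their values were seen, and no explanation of them was tested.

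The 100-kb bin of POU3F3 held 21 EZH2 peaks in KO and none in WT. Bins at 49100001 on chromosome 4 and at 143200001 on chromosome 1, without a protein-coding gene, held 27 and 21 in KO and none in WT. Leaving out bins with a score of 50 or more, the highest count in another bin without WT peaks was 8, and the highest WT count in a bin without KO peaks was 13. The highest score in the cluster was 12 with EZH2 and 9 with H3K27me3.

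Peaks with a score of 50 or more numbered 7 in WT and 104 in KO with EZH2, and 21 and 47 with H3K27me3. With EZH2 in KO, 23 of them lay between 143184860 and 143262895 on chromosome 1, 12 between 34571612 and 34595789 and 11 between 46380810 and 46401557 on chromosome 16. The EZH2 ratio of peak numbers without such peaks was 0.633.

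The genes with the highest coverage were mostly marked in both genotypes. Of the 100 genes with the highest H3K27me3 coverage in WT, 96 were marked in KO, and of the KO top 100, 99 were marked in WT. With EZH2 the counts were 97 and 96. Among the most covered genes by H3K27me3 in KO were the keratin genes KRT6A (31.5% in WT and 37.0% in KO), KRT1 (27.6% and 35.2%) and KRT6C (20.3% and 34.2%), which encode keratins of stratified epithelium. KRT6A and KRT6C are near-identical copies, so their values are uncertain. DHRS9, a retinol dehydrogenase gene, had 36.0% and 37.6%, and G0S2, an inhibitor of lipolysis, 41.0% and 38.0%.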
